A study of Mus musculus with 6 samples.

How the data were processed

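Poly(A)-selected RNA of the mouse cervical carcinoma line U14 was sequenced as paired ends in 6 libraries, 3 of wild-type cells and 3 of cells overexpressing the forkhead transcription factor FOXP1. Per the submitters' processing notes, reads were handled with Trimmomatic, HISAT2 and DESeq, with no versions given. The same notes name the human build hg19, although the labels give mouse as the organism and the gene symbols and Entrez identifiers are mouse ones. For this reason no coordinates are printed. The read counter and the annotation are not given in the sources used here.

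The deposited table lists 1722 genes, all with an authors' q-value under 0.05 and a fold of at least 2 in either direction, as checked on its values. It holds 1 expression value per gene and library, which the header calls only expression. These values were settled as FPKM, made by the authors, from the numbers themselves. Read counts rebuilt from them and from the authors' group means came out whole for 100.0% of 10332 values, within a tolerance of 0.01. The library totals were then derived as whole numbers by construction, so their being whole adds no evidence. Per the file headers, the authors also deposited the mean normalised signal of each group, which is a mean of counts divided by DESeq2 size factors. The authors' fold ratio, log2 fold change, p-value and q-value stand beside them, taken as FOXP1 overexpression over wild type. The ratio of q to p at the smallest p gave 15689 genes tested by the authors.

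Library columns were matched to samples by name. Wild-type libraries 1, 2 and 3 and overexpression libraries 2 and 3 matched a sample title. The remaining overexpression column carries the number 4, which no sample title has, so it was used as a library of its group with no number in common with any sample and is called library 4. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Every pair of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 14.1 to 25.7 in wild type and 76.0 to 162.7 in overexpression.

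The plan, fixed before the data were examined, assumed read counts. It also said what to do with a table of changed genes only: to keep the authors' scale and to report their own count of changed genes as the main count. That was done, and a gene is called higher or lower here when the authors' table lists it so. Because genes that did not pass were not analysed here, enrichment against unchanged genes by a rank or correlation-based set test was not possible, and no scaling factor was estimated over the listed genes for the main result. The plan also fixed 34 gene lists, with 920 entries. For each, the members listed as higher or lower were counted, along with the count adjusted over the list alone, in which unlisted members were given a p of 1. The split of higher and lower members was compared with that of the other listed genes by a two-sided Fisher's exact test, Benjamini-Hochberg adjusted over the 13 lists with at least 5 listed members. A one-sided hypergeometric test of how many members were listed, among the 15689 genes tested, was added after the data had been seen. It takes every member as tested and genes as independent, and was adjusted over all 34 lists.

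Genes named in the text follow a rule fixed in advance. It takes the 12 largest rises and 12 largest falls in the authors' log2 fold, among genes whose groups did not overlap and whose mean in the higher group reached the median of that mean, leaving out predicted genes. It then takes up to 4 members with the smallest q from each list with at least 3 listed members, giving 116 genes in all. The rule did not say which mean sets the floor. Both the FPKM and the normalised signal were looked at, and FPKM was used, with a floor of 3.41. With the normalised signal, other genes would take the places of Gzmd and Fbln7 among the rises and of H4c4, H4c18 and Tm4sf1 among the falls. Results of 2 of the genes the rule names are not reported here. All other genes named were chosen after their values were seen, which is not repeated beside each of them. For cell types, 16 further marker lists were written after the table had been opened.

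As alternatives, limma's moderated test with a trend was run on log2(FPKM + 1) with Benjamini-Hochberg adjustment over the listed genes, an adjusted p under 0.05 and a log2 difference of at least 1. It was repeated without the trend, with a pseudocount of 0.1, with a filter of 1 FPKM on the mean of the higher group, on median-centred values, with the replicate number as a block, and without each library in turn. On the log2(FPKM + 1) scale the change of genes with low values is understated. Limma's voom on the rebuilt counts, with the authors' size factors as rebuilt from the table, and adjustment over all 15689 genes were added after the data had been seen. Unless said otherwise, calls of limma and voom are adjusted over the listed genes, which had been selected on these same libraries. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. Entrez identifiers of 1712 listed genes and symbols of 1710 matched the mouse RefSeq gene table.

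The rebuilding step was tested on simulated data of 1722 genes and returned 100.0% of the counts and all 6 library totals. Next, 200 genes of known fold were added to unchanged simulated libraries for the same comparison, and scored at an adjusted p under 0.05 with no fold threshold. The limma trend fit called 59.0% of the 100 genes changed 2-fold and 98.0% of those changed 4-fold, and 10 of 1522 unchanged genes. For voom these were 64.0%, 100.0% and 8. The simulation gave all genes and both groups the same spread and left most genes unchanged. These rates therefore do not carry over to the calls in the results, which also need the fold threshold. Totals behind the FPKM values were 16824351 to 20410060 fragments per library, so that 1 fragment in a gene of 1 kb was worth 0.0490 to 0.0594 FPKM. Genes in near-identical families (histone genes, Hspa1b, Ccl21a, Lyz1 and Lyz2, Bcl2a1b, and the H2 genes) can share reads, and their values are uncertain to that extent.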

Results

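The series asked which genes differ in expression between U14 cells, a mouse cervical carcinoma line, and U14 cells that overexpress FOXP1, a forkhead transcription factor. Steady-state mRNA was measured in 3 wild-type and 3 overexpression libraries. The totals behind the FPKM values were 18656771, 18668395 and 17994311 fragments in wild-type libraries 1, 2 and 3, and 16824351, 20410060 and 17744093 in overexpression libraries 2, 3 and 4. The ratio of their mean in overexpression to that in wild type was 0.99. The genes listed as changed held 5.47% to 6.41% of the fragments in wild type and 11.70% to 12.85% in overexpression. The level of Foxp1 itself was not analysed here, so the labels were not checked against it.

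Genes higher in the FOXP1-overexpression libraries far outnumbered those that were lower. Among the most abundant, the lysozyme gene Lyz2 (Entrez 17105) rose from 1304 ± 309 FPKM (SD, n = 3) to 5934 ± 1229 (SD, n = 3), and Cd74 (Entrez 16149), the invariant chain of MHC class II, from 1657 ± 253 to 4508 ± 220. The stromal proteoglycan gene Dcn (Entrez 13179) rose from 82.2 ± 5.09 to 288 ± 72.5 FPKM. The epithelial keratin gene Krt18 (Entrez 16668) fell from 351 ± 37.4 to 155 ± 21.3 FPKM.

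The authors' deposited table lists 1505 genes as higher and 217 as lower, out of 15689 genes tested, and 87.4% of the listed genes are higher. Their median log2 fold in the authors' deposited table was 1.46 for the higher genes and -1.20 for the lower ones, with extremes of 6.40 and -5.36. In 1602 of the 1722 listed genes (93.0%) the 2 groups did not overlap, where chance gives 10% for 3 against 3. These genes had been selected for their difference, so that share is not independent evidence. Libraries of overexpressing cells differed more among themselves, with a median SD of log2(FPKM + 1) of 0.24 against 0.16 in wild type. When each library was centred on the median of the listed genes, which removed a shift of 0.81 on the log2 scale, limma called 26 genes higher and 213 lower. By construction, 878 listed genes then lay above 0 and 844 below. With limma on the uncentred FPKM values and adjustment over the listed genes, 628 were called higher and 71 lower.

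**Figure D1:**
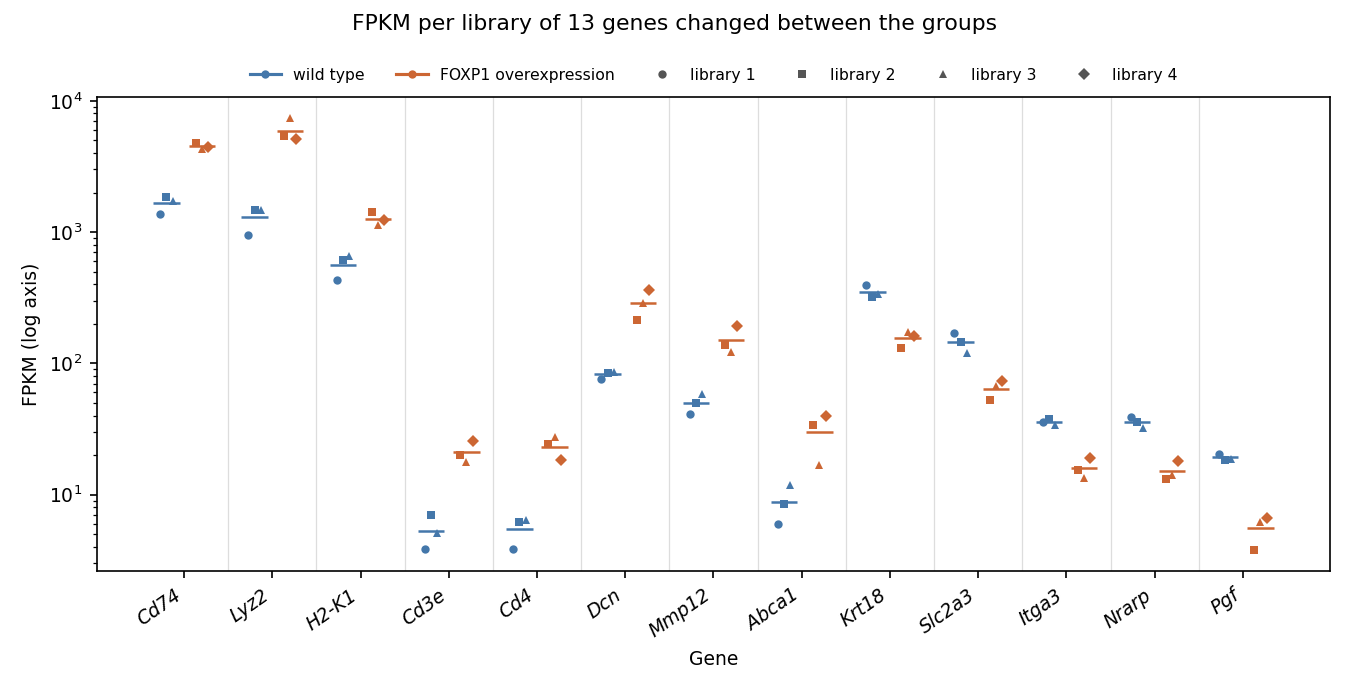
FPKM on a log axis of 13 genes in the 3 wild-type and 3 FOXP1-overexpression libraries; points are single libraries and horizontal lines are group means. In each of the 13 genes the groups did not overlap, as for Cd74 at 1657 ± 253 FPKM in wild type and 4508 ± 220 in overexpression.

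Antigen presentation genes rose together. Of the 8 genes of the MHC class II list, 8 rose (8 adjusted over the list alone), with a median log2 fold of 1.38 in the authors' deposited table. The transactivator Ciita, which switches on the class II genes, rose from 4.15 ± 0.986 FPKM (SD, n = 3) to 13.2 ± 0.806, H2-Ab1 from 989 ± 161 to 2632 ± 363, and H2-Aa from 860 ± 124 to 2315 ± 562. Of the 24 genes of the MHC class I and antigen processing list, 10 rose, none fell and 14 were not listed as changed (10 adjusted over the list alone). Its members included the class I heavy chains H2-K1 (565 ± 121 to 1260 ± 147 FPKM) and H2-Q4 (73.8 ± 10.7 to 159.8 ± 24.7 FPKM), and Cd274, the ligand PD-L1 (16.2 ± 2.98 to 42.3 ± 9.79 FPKM). More members were listed than a random draw of tested genes would give, with a Benjamini-Hochberg adjusted p of 7.06e-07 for class II and 9.65e-04 for class I in the hypergeometric test, which was chosen after the data had been seen. Of the 53 interferon-stimulated genes, 1 was listed, Gbp5, which was named after its value was seen and rose from 25.1 ± 6.06 to 54.1 ± 15.7 FPKM. In voom on the rebuilt counts, H2-K1 was no longer past the fold threshold without wild-type library 1 (log2 fold 0.92) and just under it without overexpression library 2, and H2-Q4 without wild-type library 1 (0.93) or overexpression library 4 (0.97). The calls of the class I list in voom went from 10 to 2 without wild-type library 1 and to 5 without overexpression library 2.

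Markers of leukocytes moved with the antigen presentation genes. Of the 26 genes of the fixed leukocyte and macrophage list, 13 rose, none fell and 13 were not listed (13 adjusted over the list alone), with a median log2 fold of 1.60 in the authors' deposited table and an adjusted p of 1.43e-05 in the hypergeometric test. The T cell receptor component Cd3e rose from 5.32 ± 1.57 FPKM (SD, n = 3) to 21.1 ± 4.22, the T cell coreceptor Cd4 from 5.50 ± 1.42 to 23.2 ± 4.63, and the pan-leukocyte phosphatase Ptprc from 29.1 ± 7.39 to 68.4 ± 9.12. Without wild-type library 1, 8 of these 13 genes were called in voom, and the log2 fold of Ptprc fell under 1, at 0.98. Transcripts of this kind were present in the wild-type libraries as well, where the lowest median over the listed T cell markers in any library was 2.73 FPKM and that of the listed macrophage markers was 89.9 FPKM.

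In the marker lists written after the table had been opened, 21 of 27 T cell markers, 14 of 18 B cell markers, 8 of 14 plasma cell markers, 6 of 10 markers of natural killer and cytotoxic cells, 10 of 25 macrophage markers and 8 of 17 dendritic cell markers were listed, in each case as higher. The same held for 7 of 11 mast cell and eosinophil markers, 2 of 10 neutrophil markers and 4 of 11 germinal centre B cell markers. Outside the leukocytes, 8 of 14 fibroblast, 6 of 8 lymphatic endothelium, 2 of 15 skeletal muscle, 3 of 7 nerve and 2 of 9 lung epithelium markers rose. None of the 5 blood endothelium markers and 1 of the 9 adipocyte markers was listed, and none of the 15 genes of the fixed endothelial list.

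**Figure D2:**
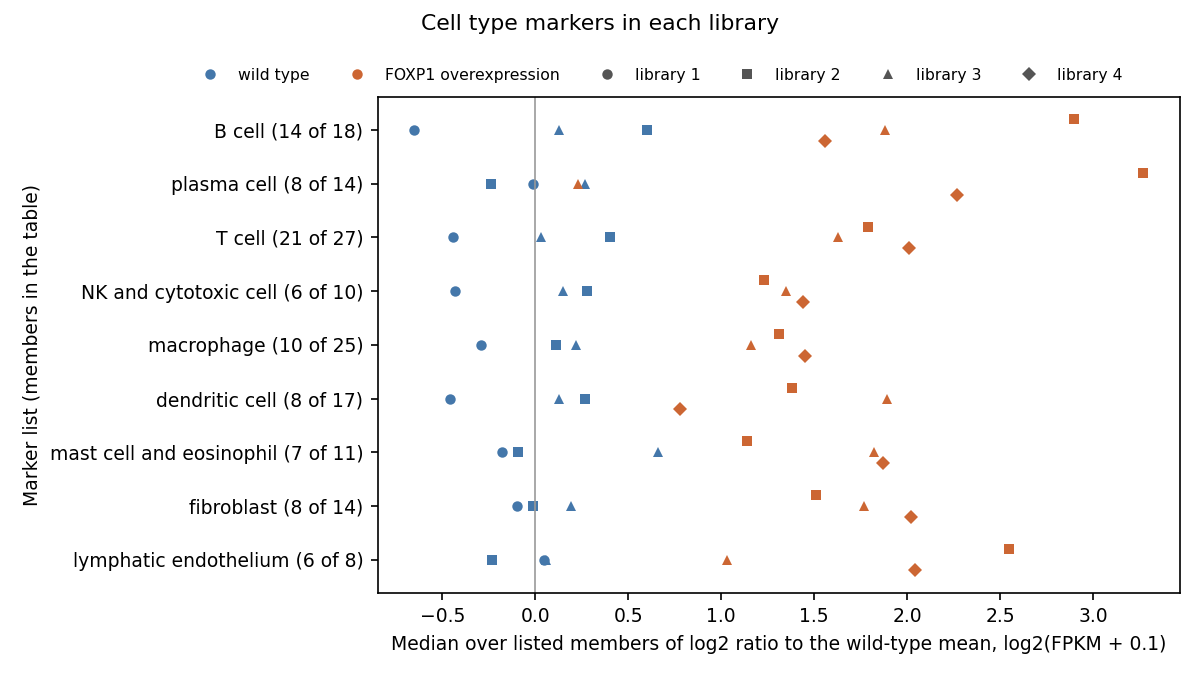
Median over the listed members of 9 marker lists of the log2 ratio of a library to the wild-type mean, on the log2(FPKM + 0.1) scale; each point is 1 library, in wild type (libraries 1 to 3) or FOXP1 overexpression (libraries 2 to 4). Plasma cell markers lay at 3.27 and 2.27 in overexpression libraries 2 and 4 and at 0.23 in library 3, whereas T cell markers lay at 1.79, 1.63 and 2.01 in libraries 2, 3 and 4.

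Most listed genes of the extracellular matrix and fibroblast lists rose, though only the protease list passed the hypergeometric test. Of 32 extracellular matrix protease genes and inhibitors, 12 rose, 1 fell and 19 were not listed (13 adjusted over the list alone), with an adjusted p of 1.69e-04 in the hypergeometric test. The lysosomal protease gene Ctss rose from 539.5 ± 94.1 FPKM (SD, n = 3) to 1802 ± 188, the macrophage elastase Mmp12 from 50.03 ± 8.53 to 150.5 ± 36.2, Adam19 from 3.58 ± 0.287 to 9.42 ± 2.52 and the gelatinase Mmp9 from 1.33 ± 0.247 to 4.52 ± 1.26. In voom 8 of the 13 were called without wild-type library 1 and 8 without overexpression library 4. The gene that fell was the inhibitor Timp1, named after its value was seen, from 119.9 ± 23.4 to 60.1 ± 5.84 FPKM. Of 15 fibroblast markers, 4 rose and none fell (4 adjusted over the list alone; adjusted hypergeometric p of 0.209), among them Dpt, from 39.8 ± 10.7 to 132 ± 17.5 FPKM, and Lum, from 17.5 ± 2.57 to 69.2 ± 36.7 FPKM. Of 24 collagens, 4 rose (3 adjusted over the list alone, with an adjusted hypergeometric p of 0.533), of which Col6a1 was the most abundant at 27.9 ± 4.22 and 61.8 ± 24.5 FPKM. After median centring 3 of these 4 collagens lay below 0, against 844 of all 1722 listed genes by construction. The call of Col6a1 in voom was lost without wild-type library 3 (log2 fold 0.87), overexpression library 2 (0.92) or overexpression library 4 (0.77). Of the 4 collagens, voom called 3 on all 6 libraries, 2 without wild-type library 1, wild-type library 2 or overexpression library 2, 1 without wild-type library 3 and 0 without overexpression library 4 (2 at an unadjusted p under 0.05). On all 6 libraries with adjustment over every gene tested, voom called 0 of them (3 at an unadjusted p under 0.05). Col4a6, at 0.0885 ± 0.0869 FPKM in overexpression, was not past the thresholds of voom on all 6 libraries.

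Integrins moved in both directions. Of 20, 4 rose, 2 fell and 14 were not listed (6 adjusted over the list alone; adjusted hypergeometric p of 0.084). Itga3 and Itga6, subunits of laminin receptors on epithelial cells, fell from 35.8 ± 1.98 to 15.9 ± 2.76 FPKM and from 71.4 ± 5.32 to 35.5 ± 6.40 FPKM (SD, n = 3 in each group). Itgb2, the shared chain of leukocyte integrins, rose from 66.9 ± 18.7 to 174 ± 26.5 FPKM and Itga4 from 3.80 ± 0.883 to 14 ± 6.27 FPKM. Without overexpression library 3, Itga6 was not past the fold threshold in voom (log2 fold -0.97). Of 28 epithelial genes, 2 rose and 2 fell (4 adjusted over the list alone): Krt18 and the transcription factor Elf3 (2.74 ± 0.496 to 1.09 ± 0.160 FPKM) fell, while the adhesion gene Epcam rose from 1.25 ± 0.0665 to 6.01 ± 2.84 FPKM. Of 26 mesenchymal genes, 2 rose and 1 fell (3 adjusted over the list alone), the rises being those of Thy1 and Cdh11. In voom Thy1 was not past the fold threshold without overexpression library 4 (log2 fold 0.79), nor Cdh11 without wild-type library 3 (0.69) or overexpression library 2 (1.02, with an adjusted p above 0.05) or 4 (0.87). Without overexpression library 4 voom called 0 of the 3 mesenchymal genes (2 at an unadjusted p under 0.05).

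Among secreted signals, 7 of 28 chemokines rose, 1 fell and 20 were not listed (8 adjusted over the list alone; adjusted hypergeometric p of 0.049). The T cell attractant Ccl5 rose from 139 ± 54.4 FPKM (SD, n = 3) to 471 ± 56.1, Cxcl12 from 16.9 ± 2.53 to 46.4 ± 7.36, and the interferon-induced Cxcl9 from 85.1 ± 9.57 to 206 ± 61.1. The log2 fold of Cxcl9 in voom was 0.99 without overexpression library 4. The chemokine gene that fell was the platelet gene Ppbp, named after its value was seen, whose wild-type libraries read 8.07, 0.297 and 1.85 FPKM. Of 49 cytokines and growth factors, 7 rose and 2 fell (8 adjusted over the list alone; adjusted hypergeometric p of 0.217). Igf1 rose from 2.62 ± 0.194 to 10.3 ± 3.41 FPKM and Ltb from 17.1 ± 8.26 to 65.7 ± 6.18, and the EGF receptor ligand Areg fell from 51.6 ± 8.93 to 21.96 ± 1.87. Of 40 axon guidance genes, 8 rose and 3 fell (11 adjusted over the list alone; adjusted hypergeometric p of 0.021), and after median centring 6 lay above 0 and 5 below. Sema4d rose from 9.69 ± 2.03 to 22.7 ± 4.40 FPKM and Nrp2 from 5.51 ± 1.03 to 14.2 ± 5.06, whereas the ephrin gene Efna1 fell from 35.3 ± 4.48 to 15.5 ± 3.64.

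Developmental signalling lists moved in part. Of 41 Wnt pathway genes, 9 rose and none fell (7 adjusted over the list alone, with an adjusted hypergeometric p of 0.132). After median centring 6 of the 9 lay below 0, Axin2, Lef1 and Znrf3 among them, as did 844 of all 1722 listed genes by construction. Genes of low FPKM can fall below 0 there despite a large fold, so this sign says little about the list. The receptor gene Fzd1 rose from 2.69 ± 0.404 FPKM (SD, n = 3) to 8.33 ± 3.31, while the Wnt target Axin2 stood at 0.290 ± 0.115 and 1.02 ± 0.504 FPKM and lost its call in voom without wild-type library 1 (log2 fold 1.37). Voom called 8 of the 9 on all 6 libraries and 4 without wild-type library 1, and limma's trend fit called 2. When adjusted over every gene tested, voom called 2. In the Notch pathway, 3 of 21 genes fell and 1 rose (4 adjusted over the list alone; adjusted hypergeometric p of 0.468). The ligand genes Dll4 and Dll1 fell from 7.08 ± 0.468 to 3.31 ± 0.278 FPKM and from 16.3 ± 3.18 to 7.43 ± 2.02 FPKM, and the Notch target Nrarp from 35.8 ± 3.41 to 15.1 ± 2.63. Of 36 Hox genes, 5 rose (4 adjusted over the list alone), all at low levels, with Hoxc8 the highest of the 4 named at 0.970 ± 0.172 and 2.65 ± 0.710 FPKM. After median centring 4 of the 5 lay below 0, Hoxc6, Hoxd9 and Hoxd10 among them, against 844 of all 1722 listed genes. A low FPKM bears on this sign: Hoxd10 had an authors' log2 fold of 4.79 but a log2 difference of 0.26 in limma's trend fit before centring. Voom called 5 of the Hox genes on all 6 libraries and limma's trend fit 0 (5 at an unadjusted p under 0.05).

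The falls included genes of nutrient uptake and stress. Of 35 glycolysis and hypoxia genes, 3 fell and none rose (3 adjusted over the list alone): the glucose transporter Slc2a3, from 145 ± 24.8 to 64.1 ± 10.8 FPKM (SD, n = 3 in each group), the hypoxia-induced Ndrg1, from 239 ± 22.9 to 103 ± 29.2, and the carbonic anhydrase Car12, from 8.77 ± 0.648 to 3.47 ± 1.29. Of 16 heat shock genes, 3 fell (3 adjusted over the list alone), with Hspa1b at 42.0 ± 23.6 and 11.2 ± 4.001 FPKM. Of 34 genes of cholesterol and fatty acid synthesis, 2 fell and 1 rose (2 adjusted over the list alone), and Sqle, an enzyme of sterol synthesis, fell from 97.6 ± 8.05 to 47.8 ± 16.0 FPKM. The monocarboxylate transporter Slc16a1 fell from 68.7 ± 8.25 to 32.2 ± 5.04 FPKM and the cholesterol exporter Abca1 rose from 8.79 ± 2.95 to 30.1 ± 11.8, in a list of 22 transporters with 2 rises and 2 falls (4 adjusted over the list alone). None of these 4 lists passed the hypergeometric test of how many members were listed, with adjusted p-values of 0.987, 0.533, 0.987 and 0.491. That test counts higher and lower genes together, so it cannot decide whether falls alone were more frequent in these lists. The number of falls alone was not tested. In voom Sqle was not past the fold threshold without overexpression library 2 (log2 fold -0.92), nor were Dnajb1 and Hsph1, the other heat shock genes, without wild-type library 2 (-0.89 and -0.87). Leaving out overexpression library 4 had the same result for Dnajb1 (-0.90), as did leaving out overexpression library 2 for Hsph1 (-0.98), with a value just short of -1 without library 4. Voom thus called 1 of the 3 heat shock genes without wild-type library 2 and 1 without overexpression library 4. Without overexpression library 2 it called 1 of the 3 genes of the synthesis list and 2 of the 4 transporters.

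Of 30 genes of the integrated stress and unfolded protein responses, 5 rose and 2 fell (7 adjusted over the list alone; adjusted hypergeometric p of 0.152). Voom called 4 of the 7 on all 6 libraries, and 3 without wild-type library 1, overexpression library 2 or overexpression library 4. The median log2 ratio of the 7 to the wild-type mean was 1.66, 0.20 and 1.16 in overexpression libraries 2, 3 and 4, and 6 of them were higher in library 2 than in library 3. The serine synthesis gene Psat1 fell from 194.5 ± 15.3 FPKM (SD, n = 3) to 97.4 ± 19.0 and the amino acid transporter Slc7a5 from 132 ± 17.2 to 62.8 ± 13.8, while the cystine transporter Slc7a11 rose from 1.61 ± 0.187 to 5.07 ± 0.328. Xbp1, a factor of secretory cells, read 404 and 271 FPKM in overexpression libraries 2 and 4 and 96.7 in library 3, with wild-type libraries at 69.6 to 86.4, and lost its call in voom without wild-type library 1 (log2 fold 1.43). The log2 fold of Psat1 in voom was -0.98 without overexpression library 2 and just short of -1 without library 4. Of 26 NRF2 targets, 6 rose (6 adjusted over the list alone; adjusted hypergeometric p of 0.180), among them Ephx1, from 6.24 ± 1.04 to 19.7 ± 2.84 FPKM. Of 28 immediate-early genes, 2 rose and 2 fell (4 adjusted over the list alone), with Myc at 207 ± 29.8 and 107.5 ± 25.8 FPKM. In voom the log2 fold of Myc was -0.90 without wild-type library 2, -0.93 without overexpression library 2 and -0.97 without overexpression library 3. It called 2 of the 4 immediate-early genes without wild-type library 2 and 2 without overexpression library 4. Of 35 cell cycle genes, Myc fell and Ccnd2 rose (2 adjusted over the list alone). Of 27 cell cycle inhibitors and p53 targets, 4 rose (4 adjusted over the list alone, with an adjusted hypergeometric p of 0.599), with Btg2 at 9.21 ± 1.03 and 31.8 ± 17.1 FPKM. Voom called 4 of them on all 6 libraries, and 0 when adjusted over every gene tested, as did limma's trend fit so adjusted. Their median log2 ratio to the wild-type mean was 2.08, 0.81 and 2.04 in overexpression libraries 2, 3 and 4, and all 4 were higher in library 2 than in library 3. Of 26 apoptosis genes, 3 rose (3 adjusted over the list alone): Bcl2a1b, Bmf and Tnfsf10. Voom called 1 of them without wild-type library 1, where the log2 fold was 0.97 for Bcl2a1b and 0.91 for Tnfsf10, and limma's trend fit called 1 on all 6 libraries. Adjusted over every gene tested, voom also called 1 on all 6 libraries. Bcl2a1b was also lost in voom without overexpression library 3 (0.89), Bmf without overexpression library 2 (0.83) and Tnfsf10 without wild-type library 2 (0.97) or overexpression library 4 (0.79). Of 26 muscle and neural markers, 6 rose (5 adjusted over the list alone). Voom called 4 of these 6 on all 6 libraries, 2 without wild-type library 2 and 3 without wild-type library 1, overexpression library 2 or overexpression library 4, and limma's trend fit called 0 (3 at an unadjusted p under 0.05).

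The muscle genes Myh3 and Myh8 were under 0.1 FPKM in wild type and reached 0.824 and 1.33 FPKM in overexpression library 2, with at most 0.226 FPKM in libraries 3 and 4, and neither was past the thresholds of voom on all 6 libraries. Of 26 genes of the TGF-beta response, 1 rose and 1 fell (2 adjusted over the list alone). Of 23 histone genes, 2 fell (0 adjusted over the list alone), and of 23 forkhead genes 1 was listed (0 adjusted over the list alone). No member of the ribosomal protein (32 genes), mitochondrially encoded (15) or sex-linked (10) lists was listed as changed. None of the 13 lists with at least 5 listed members differed from the other listed genes in its split of higher and lower members. The lowest p was 0.152 and the lowest adjusted p 0.941 in Fisher's exact test. Lists with fewer listed members were not tested for their split. Among them, heat shock and glycolysis and hypoxia each had 0 higher and 3 lower, and the Notch pathway 1 and 3. Fibroblast markers and collagens each had 4 higher and 0 lower.

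**Figure D3:**
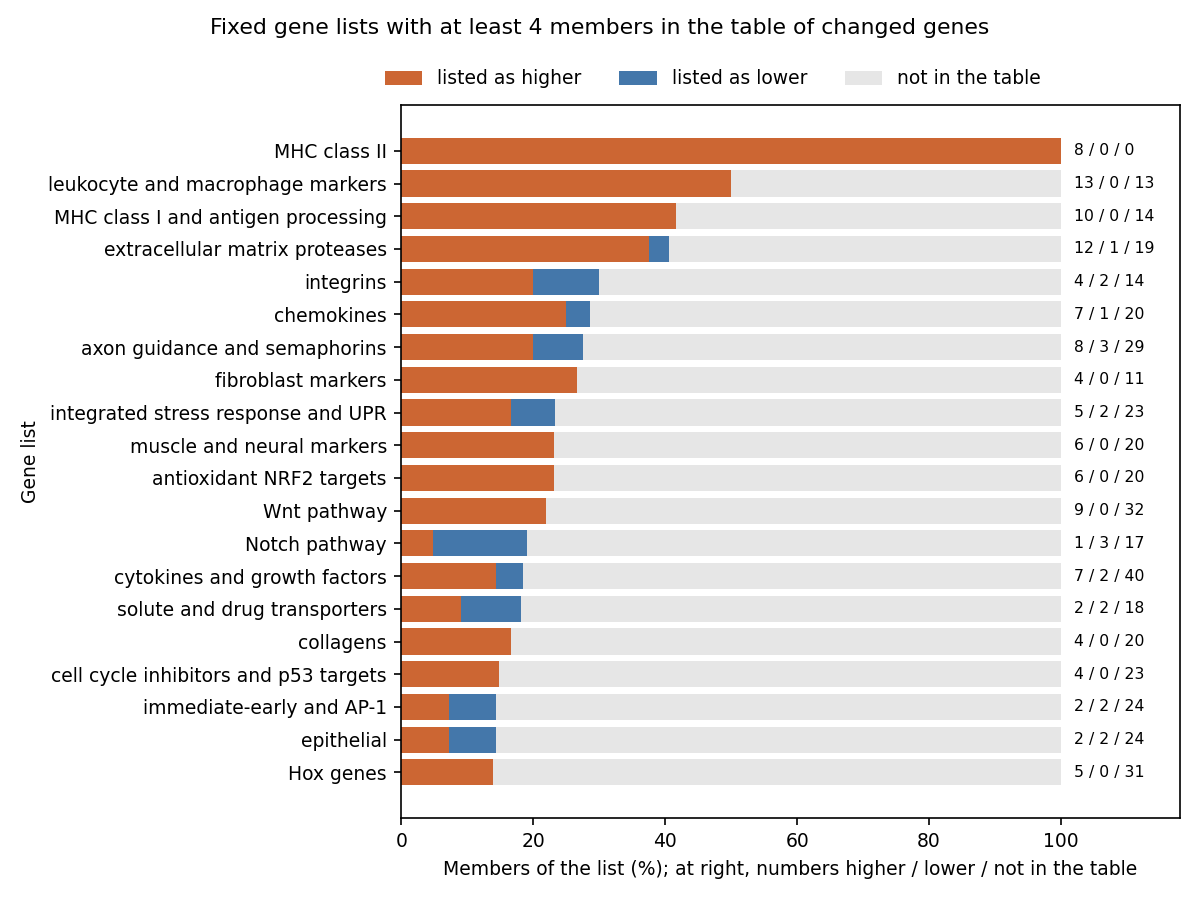
Share of the members of each fixed list, in percent, listed as higher, listed as lower or not in the table of changed genes, for the 20 lists with at least 4 listed members; numbers at the right give the counts in that order. MHC class II stands first with 8 of 8 genes higher, and the Notch pathway has 3 lower and 1 higher.

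The largest rises were uneven between overexpression libraries. The lymphoid chemokine gene Ccl21a had the largest fold by the naming rule, with a log2 fold of 5.67 and q of 1.23e-04 in the authors' deposited table. Its FPKM read 49.4, 2.20 and 13.6 in overexpression libraries 2, 3 and 4 and at most 0.803 in wild type. Lyz1 and the methyltransferase gene Inmt read 384 and 69.1 FPKM in library 3, against 77.8 and 9.65 in library 2 and 41.2 and 7.82 in library 4. Lax1, an adaptor of lymphocyte signalling, was high in libraries 2 and 4 (56.0 and 29.4 FPKM) and lower in library 3 (8.06). More even rises were those of the growth factor Ptn, from 1.40 ± 0.803 FPKM (SD, n = 3) to 20.6 ± 12.3, of Apol7c, from 1.46 ± 0.622 to 17.7 ± 6.24, and of Atp6v0d2, a proton pump subunit, from 2.96 ± 1.84 to 21.6 ± 2.03. The remaining rises were Hepacam2, Ear2, Stac2, Gzmd and Fbln7, with log2 folds of 3.21, 2.94, 2.86, 2.76 and 2.73 in the authors' deposited table. In voom, Ccl21a was no longer past the threshold on the adjusted p when any 1 of the 3 wild-type libraries was left out, with log2 folds of 5.50, 4.31 and 4.88 without libraries 1, 2 and 3. The same held for Gzmd (2.29, 2.05 and 2.36), and Hepacam2 (2.43) and Inmt (3.41) were not past it without wild-type library 1.

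The largest falls by the naming rule were smaller in size than the rises and mostly more even. Hspa1b had the largest, with a log2 fold of -1.97 in the authors' deposited table, and was uneven in wild type (31.61, 69.05 and 25.45 FPKM in libraries 1, 2 and 3). Falls outside the rule reached a log2 fold of -5.36. Placental growth factor, Pgf, fell from 19.2 ± 1.18 FPKM (SD, n = 3) to 5.55 ± 1.52, the steroid reductase gene Srd5a1 from 13.8 ± 2.77 to 4.51 ± 1.17, and Tm4sf1 from 115 ± 23.3 to 44.2 ± 7.87. Rundc3a fell from 6.66 ± 0.0974 to 2.14 ± 0.664 FPKM, the collagenase gene Mmp1b from 7.83 ± 1.71 to 2.44 ± 1.05, and the fructose transporter Slc2a5 from 5.82 ± 0.635 to 2.07 ± 0.439. Prg4, Dynap and Ptprn had log2 folds of -1.69, -1.57 and -1.47 in the authors' deposited table. H4c4 and H4c18, which are near-identical histone H4 genes, had -1.87 and -1.71 in the authors' deposited table and are uncertain for that reason. They also rested on few fragments per library. H4c4 had 29 to 48 in wild type and 6 to 17 in overexpression, and H4c18 had 19 to 31 and 7 to 9. Of the 116 genes named by the rule, 113 were past the thresholds of voom on all 6 libraries, 76 stayed past them whichever library was left out, and 85 were past those of limma's trend fit on log2(FPKM + 1).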

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

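The voom fits, the adjustment over 15689 genes and the fit of libraries 2 and 3 without a block were chosen after seeing the data. The count of 1722 changed genes was 1336 at an authors' q under 0.01, 1511 with a pseudocount of 0.1 and 1620 with voom. It was 311 at a fold of 4, 699 with limma's trend, 681 without it, 702 with the filter of 1 FPKM, 534 and 910 when limma and voom were adjusted over every gene tested, 514 to 786 when limma left out 1 library and 1184 to 1585 when voom did. Leaving out wild-type library 1 gave the lowest counts in both. Genes of the fixed lists went from 158 to 26 at a fold of 4, 101 with limma's trend, 100 without it, 101 with the filter, 73 and 98 with adjustment over every gene tested, 78 to 109 when limma left out 1 library and 106 to 146 when voom did. No list with at least 5 called members split unlike the other called genes in any setting, and smaller lists were not tested. The log2(FPKM + 1) scale shrinks low genes, and adjusting over more genes costs calls by construction. Leaving out 1 library did not always cost calls. With limma's trend fit, 786 genes were called without wild-type library 3 and 768 without overexpression library 3, against 699 with all libraries. Leaving out any other library gave fewer, 514 to 686, and in voom every such count was below 1620. Other causes were not tested.

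Median centring left 239 genes, 37 of them in the fixed lists, with 10.9% higher. It subtracts the median of genes selected as changed, so it removes most of the effect by construction, and it left 844 of the 1722 listed genes below 0. It turned the sign of 15 named genes: Axin2 (-0.19), Col27a1 (-0.27), Col4a6 (-0.69), Col7a1 (-0.43), Dsg2 (-0.24), Eda2r (-0.34), Fads2 (-0.02), Hoxc6 (-0.06), Hoxd10 (-0.55), Hoxd9 (-0.13), Lef1 (-0.09), Mef2c (-0.27), Myh3 (-0.49), Myh8 (-0.34) and Znrf3 (-0.10). These signs can reflect a low FPKM, since the change of such genes is understated on the log2(FPKM + 1) scale. No gene called in any of the settings had the opposite direction to the deposited table. That outcome was largely fixed in advance and is no independent evidence. The genes had been selected at a fold of at least 2 on these same libraries. A call needed a log2 difference of at least 1, more than the shift of 0.81 removed by centring.

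Only numbers 2 and 3 occur in both groups. Deviations of libraries with the same number correlated at 0.02 and 0.08 across the listed genes and those of different number at -0.03 and 0.00. These values show no sign of pairing. They cannot exclude a shared culture or batch, since only genes selected as changed between the groups entered. With the replicate block on these 4 libraries 410 genes were called, 64 of them in the lists, and without the block 428 and 65. Apart from voom on the rebuilt counts, alternatives that need read counts were not run, nor were those of the level of Foxp1. With no fold threshold, limma's trend fit on all 6 libraries called 1629 of the listed genes, against 699 with it. Other fits were not counted without that threshold. Depth limits genes near 1 fragment, such as Hoxd10, at 0 FPKM in 2 wild-type libraries.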

Other observations

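All tests in this part were chosen after the data had been seen. The annotation columns of the deposited table gave further gene groups, tested for their split of higher and lower genes against the other annotated listed genes by Fisher's exact test with Benjamini-Hochberg adjustment within each column. Of 58 listed genes of the C2H2 zinc finger family, 57 were higher (adjusted p = 0.016, 2 families tested), against 90.0% of all listed transcription factor genes. They include lymphoid factors such as Ikzf1, at 6.11 ± 1.69 and 16.2 ± 2.14 FPKM (SD, n = 3), and Ikzf3. The exception was Zfp979, which fell from 10.6 ± 1.72 to 4.97 ± 0.480 FPKM. Homeobox genes had a smaller share of higher genes than the other listed factors, with 14 higher and 5 lower (adjusted p = 0.024), the lower ones being Dlx1, Isl2, Lhx3, Msx3 and Rhox2h.

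Of 491 terms of gene ontology, 2 passed: immune system process, with 123 genes higher and 2 lower (adjusted p = 0.007), and adaptive immune response, with 74 higher and 0 lower (adjusted p = 0.020). Within them, the T cell checkpoint genes Pdcd1, Ctla4 and Lag3 rose from 5.76 ± 1.27 to 21.6 ± 6.69, from 3.13 ± 0.230 to 11.03 ± 2.07 and from 7.14 ± 2.34 to 19.0 ± 1.60 FPKM (SD, n = 3 in each group). Of 140 pathways, 1 passed, the 10 genes annotated with alcoholism, with 4 higher and 6 lower (adjusted p = 0.034), in which 5 of the 6 lower genes are histone genes (H2ac13, H2bc3, H3c8, H4c4 and H4c18). These histone genes can share reads with their copies, and H4c4 and H4c18 rested on few fragments, at most 48 and 31 in any library.

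Leukocyte marker genes were present in wild-type libraries and higher in overexpression libraries, although the labels name a single cell line. Of the 9 leukocyte marker lists, 8 had a median of at least 1 FPKM over their listed members in every wild-type library, the germinal centre list being the exception at 0.415 FPKM, so RNA of leukocytes in the samples is a candidate explanation. Whether a lower share of U14 cells raised all other cells alike stays open, except for plasma cells. The median log2 ratio of the listed plasma cell markers minus that of T cell markers was 1.49, -1.40 and 0.26 in overexpression libraries 2, 3 and 4. In wild-type libraries 1, 2 and 3 it was 0.43, -0.65 and 0.24. These values argue against an equal rise of plasma cells and T cells in overexpression libraries 2 and 3. With libraries as replicates, the difference in median log2 ratio between 2 leukocyte lists left the groups without overlap in 2 of 21 pairs, where chance gives 10% for 3 against 3. These were T cells against macrophages and against natural killer and cytotoxic cells. The count cannot decide: only members already listed as changed entered, which draws the medians together, and the pairs share lists. Other cell types were not compared, and markers not listed, such as those of endothelium, have no values here. The share of tested genes listed as higher, 9.6%, decides nothing about a factor in scaling between the groups, since the authors' size factors hold the typical gene near no change. Also open are a change in which leukocytes were present, or a change of these genes by FOXP1 itself, which the design names and which was not tested; how far U14 cells express the 80 listed markers, 11 of them also in the fixed list, was not analysed here.

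Plasma cell genes were high in overexpression libraries 2 and 4 and not in 3. Jchain, the joining chain of secreted antibodies, read 2997 and 1084 FPKM in libraries 2 and 4, 213 in library 3 and 146 to 218 in wild type, and Mzb1 read 752, 186 and 36.2 in libraries 2, 4 and 3. The median log2 ratio of library 2 over library 3 was 2.74 for the 8 listed plasma cell markers, which restates the pattern, so a different share of plasma cells between the samples stays open. The scaling or depth of library 3 is argued against by the listed T cell markers, whose median ratio was 0.18. No biological explanation was tested, since the labels name no difference between these libraries.

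Other genes were also carried by single libraries, all named after their values were seen. Foxa1, the listed forkhead gene, read 0.772 FPKM in overexpression library 3, 0.406 in library 4 and 0 in library 2, and Elf5 read 1.24, 0.217 and 0. Gsta3 read 13.1 FPKM in library 3 and 0.511 and 0.761 in libraries 2 and 4, and Tdo2 read 3.78 in library 3, 0.0364 in library 2 and 0 in library 4. Mymk, a gene of muscle cell fusion, read 1.71 FPKM in library 2, 0.164 in library 3 and 0.529 in library 4. Among the higher genes, 61 had an FPKM at least 4-fold larger in library 2 than in library 3, and 36 the reverse.

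Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many limma calls as the real one, namely the real split itself, with 699 calls against 0 at most in the others. The splits are too few for a share under 0.05, and the genes had been selected on the real split.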
